A study of Rattus norvegicus with 26 samples.

How the data were processed

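Soleus, a slow postural muscle of the lower leg, was taken from aged female rats of a pair of lines bred for low or high endurance running capacity (LCR and HCR, generation 44). Sedentary animals had no wheel, and the running animals shared cages with a wheel for more than 5 months, per the labels' protocols. The 26 libraries fall into 4 groups: 8 sedentary LCR, 8 sedentary HCR, 5 running LCR and 5 running HCR. Each library was treated as 1 animal, as the sample names and protocols describe. Runners that shared a cage were counted as separate replicates, since the fits had no term for cage. Differences of runners from sedentary rats, or between the running lines, may therefore partly be differences between cages. The labels name no batch, date or litter, and the runners are described as a cohort of their own, so a difference between cohorts cannot be separated from running.

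Libraries were made by priming from the poly(A) tail, so that reads lie near transcript 3' ends, and were read from 1 end, per the labels' protocols. The deposited table holds whole-number read counts per gene, which the authors did not normalise, as the values show. The submitters' processing notes name FastQC, MultiQC, UMI-tools, cutadapt, STAR and featureCounts without versions or settings, and the rat assembly mRatBN7.2. Whether reads with the same molecular identifier were collapsed before counting, and whether counting used the strand, is not given in the sources used here. Counting precision may therefore be lower than the totals imply, and overlapping or antisense genes, and genes with near-identical copies such as those of ribosomal proteins, are uncertain. The table has 34034 genes. Total counts ran from 1.10 to 2.52 megacounts (M) per library, and 0 columns belonged to no sample.

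Groups were taken from the group in the description and the genotype, which matched for all 26 libraries. The titles of 2 running libraries, HCR running 5 and LCR running 5, begin with the name of the other line. Both were kept under their genotype, and the comparisons were repeated with the title's line and without these libraries. Pairs of libraries of the same group were checked for duplicate deposits by a chi-square statistic over genes, and none agreed within sampling noise.

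Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, TMM factors, the filterByExpr filter by group and Benjamini-Hochberg adjustment at 0.05. All 26 libraries entered 1 fit, with no covariate, over 10064 genes. The biological coefficient of variation was 0.156. Standard errors (SE) were computed as the size of the log2 fold change divided by the square root of F. The 6 contrasts were the line difference in sedentary and in running rats, the running difference in each line, its average over the lines, and the difference between the lines' responses. Counts scaled to library size (CPM) are given as group mean ± SD. Values on the log2 CPM scale use a prior count of 2.

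A total of 32 gene lists for energy metabolism, fibre type, cell types, stress and regulation were fixed before the data were examined, and 742 of their 747 members matched a gene of the table. They were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjustment ran over the lists of each contrast. With an estimated correlation, and with fry's test for a shared direction, 0 lists passed in any of the 6 contrasts. Fry's test of change in either direction passed 5 lists for the sedentary lines, 3 for the running lines, 1 for LCR running, 0 for HCR running, 2 for running averaged and 0 for the difference of responses. Adjusted p-values with an estimated correlation stand beside the list results. Members are counted past the threshold over all genes tested and adjusted over the list alone.

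Genes were named by a rule fixed before the data were examined. For each contrast it takes up to 8 called genes with the largest rise and 8 with the largest fall among genes with an average log2 CPM of at least 2 and a gene symbol. It adds up to 4 members with the smallest adjusted p of each list that passed or had 3 called members, and Myh7, Myh2, Myh1, Myh4, Ppargc1a, Cs, Cpt1b, Pdk4 and Vegfa whatever their p. Where fewer than 6 genes passed, the 5 of smallest p were taken. Of the genes the rule names, 2 are not reported here. Other named genes are said to be chosen after their values were seen.

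The gene tests were tried on simulated counts with 200 changed genes. The list tests were tried with 1 shifted list of 20 genes, which passed with the preset correlation, as did 1 unshifted list. The other tests were not run on simulated counts. Of genes changed 2-fold, 82.0% were recovered in the sedentary line comparison, 72.5% in the running line comparison, 77.0% and 81.5% in the LCR and HCR running comparisons, 88.0% in their average and 58.0% in the difference of responses. Of genes changed 1.5-fold, the shares were 50.5%, 25.5%, 44.0%, 38.5%, 67.5% and 6.5%. Of the genes called, unchanged ones made up 8.18%, 1.92%, 5.38%, 7.23%, 3.57% and 13.3% at 1.5-fold and 5.20%, 2.68%, 3.14%, 3.55%, 4.35% and 4.92% at 2-fold, in the same order.

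Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, voom with quality weights, no filter, a stricter filter of 20 counts on average, fits of the compared groups alone, library sizes without mitochondrial mRNAs in the list tests, the replicate number as a block, the title's line, leaving out both libraries with conflicting titles, and leaving out each of the 26 libraries. Gene order came from a RefSeq table of assembly GRCr8, not the authors' assembly, and was used only to tell which genes neighbour each other, so no coordinates are given.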

Results

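Transcript abundance was measured in soleus of 26 aged female rats. Mean total counts, in megacounts (M), were 1.80 ± 0.321 (SD, n = 8) in sedentary LCR, 1.85 ± 0.351 (n = 8) in sedentary HCR, 1.70 ± 0.280 (n = 5) in running LCR and 1.49 ± 0.321 (n = 5) in running HCR. Running and sedentary libraries differed by -0.226 M counts (2-sided permutation p = 0.0897). Ttn, which encodes the giant sarcomere protein titin, took the largest share of counts, with group means from 8.81% to 9.18%. At this depth transcripts of a few CPM rest on few counts per library.

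The first comparison asked how the lines differ without a wheel. In sedentary HCR rats, transcripts of Ackr4, a scavenger receptor for chemokines, were 9.51-fold higher than in sedentary LCR rats (log2 fold change 3.25, SE 0.39, adjusted p = 1.26e-06, edgeR quasi-likelihood test), at 9.34 ± 1.62 CPM against 0.961 ± 0.623 CPM (n = 8 each). Prmt1, the main protein arginine methyltransferase of most tissues, was lower in HCR, at 2.90 ± 0.71 CPM against 79.8 ± 39.6 CPM (log2 fold change -4.75, SE 0.68, adjusted p = 0.000263). Acad11, an acyl-CoA dehydrogenase, was higher in HCR by 1.74 (SE 0.23, adjusted p = 1.14e-05). In each of these 3 genes all 8 HCR libraries lay on the same side of the LCR mean. Reads lie near transcript 3' ends, and both lines were aligned to the same rat assembly. A sequence difference between the lines at the counted site could therefore shift counts without a change of the whole transcript. This was not tested for these or the other line genes.

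Across 10064 genes, 274 differed between the sedentary lines, 158 higher and 116 lower in HCR, of which 73 differed at least 2-fold. The largest rises in HCR also included Usp11, a ubiquitin protease (2.27, SE 0.51), Cyp2j4, a cytochrome P450 (1.95, SE 0.29), Mycbpap (1.92), Kcnk2, a background potassium channel (1.67), Rpl10a (1.67) and Zfp136 (1.66). The largest falls also included the transfer RNA gene Trnaa-agc_25 (-2.86), the interferon-induced GTPase Gbp1 (-2.49, SE 0.47) and Wdr72 (-2.16). They also included the complex I subunit Ndufs5 (-1.89), Sbsn (-1.86), Hook1 (-1.62) and Mtarc1 (-1.61). Libraries were primed from the poly(A) tail, so counts at Trnaa-agc_25 need not come from the mature transfer RNA. Larger differences lay in genes without a full symbol, chosen here after their values were seen: LOC102550339 (6.18, SE 0.47), LOC102555790 (5.80, SE 0.63) and RGD1560124 (-5.23, SE 0.51). Within LCR, Usp11 stood at 21.1 and 47.1 CPM in sedentary replicates 1 and 4 and between 1.87 and 3.75 CPM in the other 6. Leaving out LCR sedentary 7 took the count to 182. Trnaa-agc_25 lost its call under voom with quality weights (adjusted p = 0.319), and Usp11 (0.0511), Acsl1 (0.0516), Rpl6 (0.053) and Eci2 (0.0592) with the title's line.

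**Figure D1:**
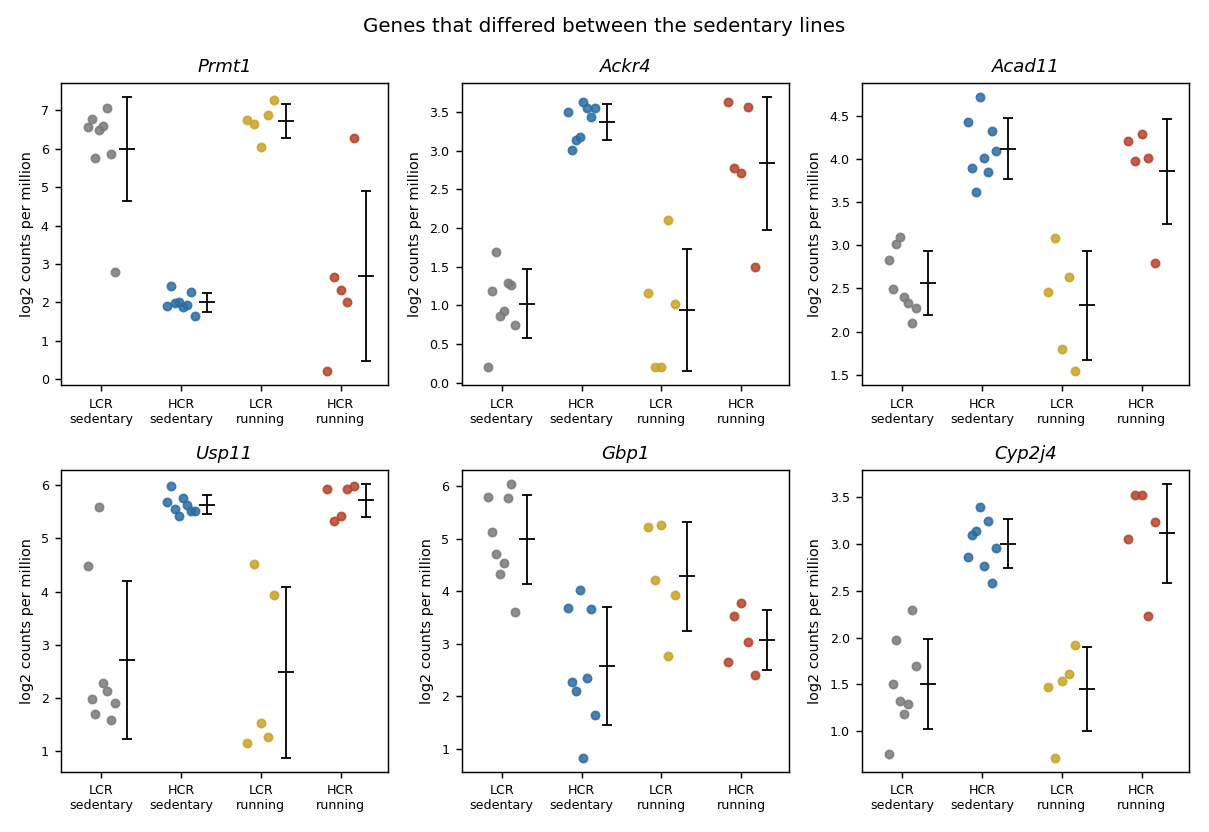
Log2 CPM (y axis) of 6 genes in each library of the 4 groups (x axis), with points for libraries and a bar for the mean and SD. HCR running 4 carries Prmt1 at 6.27, near the LCR libraries, and LCR sedentary 8 carries it at 2.79.

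Gene groups moved in the same contrast. Of 18 macrophage markers, 17 had a value above 0 in sedentary HCR (median 0.38, adjusted p = 8.55e-06, camera; 0.628 with an estimated correlation as p). The resident macrophage receptor Folr2 (0.73, SE 0.16, adjusted p = 0.00516) and the matrix protein Spp1 (1.56, SE 0.39, adjusted p = 0.0317) passed alone, Spp1 in 20 of the 26 refits without 1 library and not with only the 2 groups (adjusted p = 0.0813), and 7 members passed when adjusted over the list alone. Collagen and matrix genes had 29 of 30 members above 0 (median 0.22, adjusted p = 0.000414; p = 0.896 with an estimated correlation), of which 1 passed, the collagen chaperone Serpinh1 (0.52, SE 0.13; called in 21 of 26 refits). Adipocyte markers (median 0.38, adjusted p = 0.00236; p = 0.628 with an estimated correlation) had 0 of 11 members past the threshold, and Fabp4 stood at 0.38 (adjusted p = 0.0701) and Lep at 1.16 (adjusted p = 0.267). Fatty acid genes (median 0.10, adjusted p = 0.0175; p = 0.896 with an estimated correlation) had 2 of 32 members past it, the isomerase Eci2 (0.74) and the acyl-CoA synthetase Acsl1 (0.37). MHC class II genes (median 0.38, adjusted p = 0.0307; p = 0.896 with an estimated correlation, 0.0672 with the replicate block) had 0 of 6.

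Lists lower in sedentary HCR were glycolysis and glycogen genes (median -0.14, adjusted p = 0.00108), fast-fibre genes (median -0.27, adjusted p = 0.00108) and nuclear OXPHOS subunits (median -0.04, adjusted p = 0.0129), each with p = 0.896 with an estimated correlation. The muscle enolase Eno3 passed (-0.44, SE 0.11, adjusted p = 0.0146), as 1 of 20 glycolytic members, and 4 passed when adjusted over the list alone. No fast-fibre gene of 18 passed over all genes, with 3 when adjusted over the list alone. Tnni2, the fast troponin I, stood at -1.11 (adjusted p = 0.0762) and Myh2, the fast type 2A myosin heavy chain, at -1.08 (adjusted p = 0.206). Of 78 OXPHOS members 1 passed, Ndufs5. Among ribosomal proteins, a list that did not pass (adjusted p = 0.727), Rpl10a and Rps28 were higher and Rpl6 and Rpl19 lower in HCR. Myh7, the slow myosin heavy chain, stood at -0.16 (adjusted p = 0.499).

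The lines were compared again among runners. Myh2 was lower in running HCR than in running LCR, at 433 ± 161 CPM against 3129 ± 1511 CPM (n = 5 each), a log2 fold change of -2.86 (SE 0.59, adjusted p = 0.0207). Other fast-fibre genes fell with it: Tnni2 (-2.51, SE 0.46), the fast troponin T Tnnt3 (-1.98, SE 0.37) and the tropomyosin Tpm1 (-1.17, SE 0.28). In Myh2, Tnni2 and Tnnt3 the 5 HCR runners did not overlap the 5 LCR runners. Of 18 fast-fibre genes, 4 passed and 17 lay below 0 (median -0.39, adjusted p = 1.49e-08; p = 0.316 with an estimated correlation). Myh1 (-0.73, adjusted p = 0.853) and Myh4 (0.96, adjusted p = 0.798), myosins of faster fibres, did not pass. Slc16a3, a lactate transporter of glycolytic fibres, was lower by -2.98 (SE 0.70, adjusted p = 0.0467) in all 5 HCR runners.

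Fatty acid genes lay higher in running HCR, with 31 of 32 above 0 (median 0.38, adjusted p = 1.15e-15; p = 0.316 with an estimated correlation) and 3 past the threshold, 15 when adjusted over the list alone. Angptl4, an inhibitor of lipoprotein lipase, was higher by 4.18 (SE 0.89, adjusted p = 0.0216), at 13.7 ± 11.2 CPM against 0.682 ± 0.792 CPM, in 4 of 5 HCR runners, with a count of 0 in HCR running 4. Acsl1 was higher by 0.54 and Eci2 by 1.00, and the glycerol channel Aqp7 by 1.87. Reep6 (2.13), Abhd1 (1.99) and the desmosomal gene Dsp (1.94) also rose, with Ackr4, Cyp2j4 and Acad11 as in sedentary rats. The cytokine gene Ptn (-1.74), Cdv3l1 (-1.37), Pex3 (-1.24) and Sbsn (-1.88) fell. In all, 63 genes differed, 35 higher and 28 lower.

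**Figure D2:**
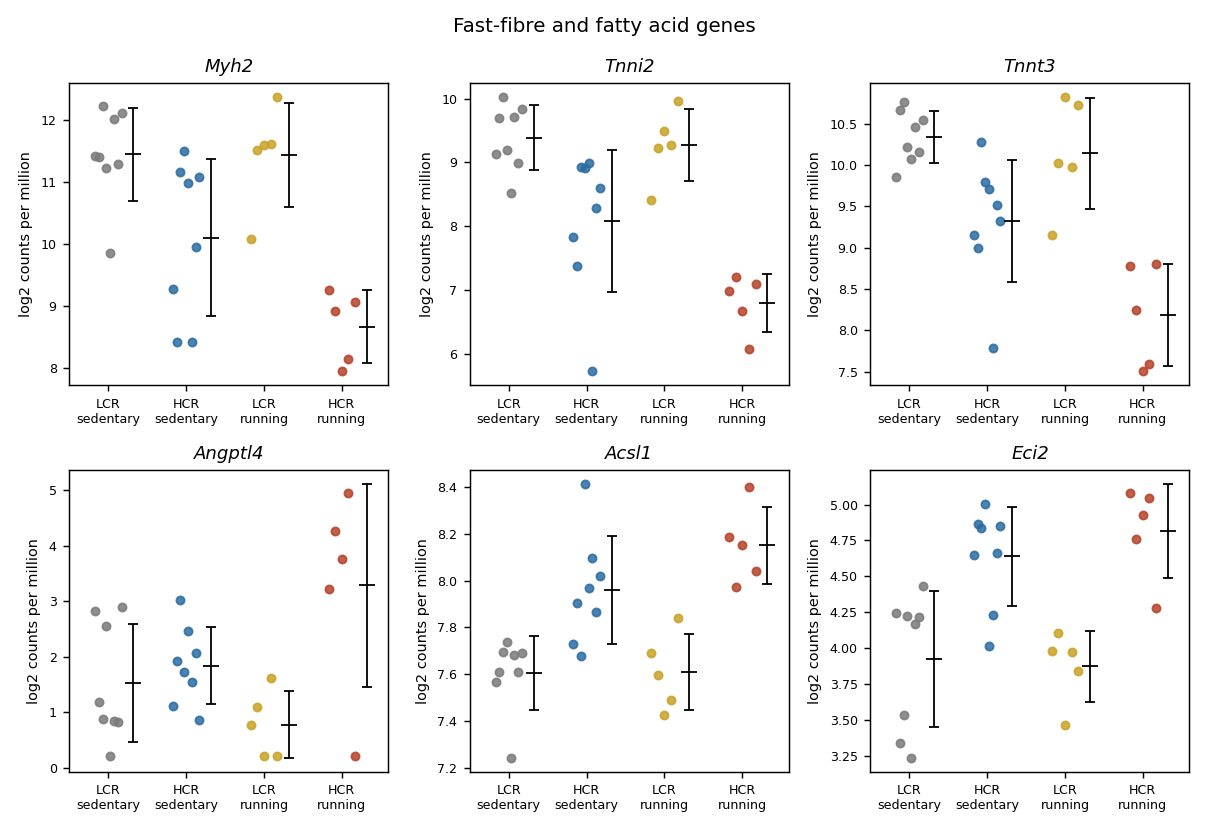
Log2 CPM (y axis) of 3 fast-fibre genes and 3 fatty acid genes in each library of the 4 groups (x axis), with points for libraries and a bar for the mean and SD. The 5 HCR runners lie below all 5 LCR runners for Myh2, Tnni2 and Tnnt3.

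Ribosomal proteins lay lower in running HCR (57 of 64 below 0, adjusted p = 2.18e-10; p = 0.776 with an estimated correlation), with Rpl6 and Rpl19 past the threshold. Collagen and matrix genes lay lower (median -0.27, adjusted p = 0.0017), as did MHC class II genes (median -0.54, adjusted p = 0.0334) and immediate early genes (median -0.23, adjusted p = 0.0258), while mitochondrially encoded mRNAs lay higher (median 0.11, adjusted p = 0.0258). For these 4 lists p = 0.776 with an estimated correlation, and 0 members passed. The count of 63 was 32 without HCR running 3, 38 without LCR running 5, 41 without LCR running 3, 0 with the title's line for the 2 conflicting libraries and 35 without them, and MHC class II genes did not pass with the replicate block (adjusted p = 0.0518). Slc16a3 and Tpm1 kept their call in 6 of 26 refits without 1 library, Aqp7 in 14, Pex3 in 16, Sbsn in 16 of 25, Rpl19 in 18, Angptl4, Eci2 and Reep6 in 20, and Abhd1, Cdv3l1 and Rpl6 in 21, against 23 for Myh2 and 26 for Tnni2 and Tnnt3.

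The line comparisons share no library. Of the 274 sedentary and 63 running calls, 38 were shared, all in the same direction, 24 higher and 14 lower, where independent lists would share 0.549 and 0.323 (Fisher's exact test across genes, p = 3.36e-44). Genes are not independent replicates, and both comparisons took the spread of each gene from the same fit, so this p may be too small. Of the 63 running calls, 62 had the same sign in sedentary rats.

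Running was compared with no wheel within each line. In HCR, 10 genes passed, all higher in runners. They included Pde4d, a phosphodiesterase that degrades cyclic AMP, at 302 ± 42.9 CPM in runners (n = 5) against 180 ± 31.7 CPM (n = 8), a log2 fold change of 0.75 (SE 0.11, adjusted p = 0.00102). Rcan2, a regulator of calcineurin (0.67, SE 0.10, adjusted p = 0.00102), rose in all 5 runners without overlap. Lmod3, an actin nucleator of the thin filament (0.56), Kyat3, a kynurenine aminotransferase (0.98), G3bp2 (0.51), Fam89b (0.48) and Eno3 (0.56) also rose. Also higher, and chosen after their values were seen, were LOC102546992 (1.04) and LOC102550339 (1.12).

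Gene lists higher in HCR runners were nuclear OXPHOS subunits, with 70 of 78 above 0 (median 0.20, adjusted p = 1.32e-17; p = 0.317 with an estimated correlation), the TCA cycle (adjusted p = 0.00244; p = 0.458), fatty acid genes (adjusted p = 0.000201; p = 0.449), glycolysis (adjusted p = 5.27e-05; p = 0.347), slow-fibre genes (adjusted p = 0.012; p = 0.449), atrophy genes (adjusted p = 0.00744; p = 0.317) and mitochondrial quality control (adjusted p = 0.00946; p = 0.379), the second p of each with an estimated correlation. Over all genes 0 OXPHOS members passed, and 16 did when adjusted over the list alone, with Uqcrh at 0.33 (adjusted p = 0.0995). Of the slow-fibre genes, Tnnc1 stood at 0.41 and Ankrd2 at -1.02. Of the atrophy genes, the ubiquitin ligase Fbxo32 stood at 0.59 (adjusted p = 0.0629).

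Lists lower in HCR runners were collagen and matrix genes, all 30 below 0 (median -0.45, adjusted p = 1.93e-10; p = 0.317), immediate early genes (median -0.42, adjusted p = 2.41e-07; p = 0.317), MHC class II (adjusted p = 0.004; p = 0.317), fast-fibre genes (adjusted p = 0.0122; p = 0.449), interferon response genes (adjusted p = 0.0122; p = 0.379), fibro-adipogenic markers (adjusted p = 0.0126; p = 0.449), Schwann cell markers (adjusted p = 0.0231; p = 0.317) and endoplasmic reticulum stress genes (adjusted p = 0.0273; p = 0.317), again with the estimated correlation second. None of their members passed over all genes. Dusp1, a phosphatase induced early by stimuli, stood at -1.05 (adjusted p = 0.0621), Fos at -1.43 (adjusted p = 0.229), Tnc at -2.03 (adjusted p = 0.183), Hspa5 at -0.44 (adjusted p = 0.0857) and Myh2 at -1.76 (adjusted p = 0.174).

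Without the 2 libraries with conflicting titles, slow-fibre genes (adjusted p = 0.0526), interferon response genes (0.0909) and endoplasmic reticulum stress genes (0.0609) did not pass. Rcan2 and Pde4d were called in all 26 refits without 1 library, Fam89b in 20 and Eno3 in 18, and Pde4d lost its call with the title's line (adjusted p = 0.0603). Of the 10 calls, 7 were kept with the title's line and 7 with the replicate block.

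DESeq2 called 79 genes, 58 higher and 21 lower, and with upper-quartile factors 10 of 14 calls were higher (71.4%). The count was 4 without HCR running 3, 38 without HCR sedentary 4, 25 without HCR running 1, 22 without HCR running 4, 19 without LCR sedentary 5 and 17 without HCR sedentary 5.

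In LCR, 0 genes passed (edgeR, smallest adjusted p = 0.067), with 612 at an unadjusted p under 0.05 against 503 expected by chance. DESeq2 called 2, Tsc22d3 and F2, and voom called 1, Tsc22d3. Tsc22d3, a glucocorticoid-induced leucine zipper gene, stood at 92.1 ± 20.8 CPM in runners (n = 5) and 60.4 ± 7.60 CPM in sedentary rats (n = 8; log2 fold change 0.61, SE 0.12). F2 stood at 1.49 (adjusted p = 0.104) and Ppargc1a, the coactivator that drives mitochondrial gene expression, at 0.69 (SE 0.17, adjusted p = 0.49). LOC120093204 (-0.94) and LOC120094342 (-0.72) followed, both with adjusted p = 0.49. The count was 2 without HCR running 4 and 1 without each of LCR sedentary 8, LCR running 4, HCR running 1 and LCR running 5.

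Lists higher in LCR runners were OXPHOS subunits, 65 of 78 above 0 (median 0.09, adjusted p = 3.68e-06; p = 0.95 with an estimated correlation), ribosomal proteins, 55 of 64 (median 0.08, adjusted p = 3.68e-06; p = 0.911), the TCA cycle (adjusted p = 0.0233; p = 0.95) and macrophage markers (median 0.20, adjusted p = 0.000788; p = 0.846). Lower were pericyte and smooth muscle markers (median -0.32, adjusted p = 0.00794; p = 0.565), endothelial markers (median -0.21, adjusted p = 0.00813; p = 0.846), heat shock genes (median -0.15, adjusted p = 0.00794; p = 0.565) and fatty acid genes (median -0.11, adjusted p = 0.0495; p = 0.95), with the estimated correlation second. Over all genes 0 members passed. Without the 2 libraries with conflicting titles the TCA cycle did not pass (adjusted p = 0.46), and with the replicate block fatty acid genes (0.368; 0.0501 with mitochondrial mRNAs left out of library sizes) and macrophage markers (0.0561) did not. Cd68, a macrophage glycoprotein, stood at 0.79 (adjusted p = 0.541) and Acta2, smooth muscle actin, at -0.56 (adjusted p = 0.706).

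Averaged over both lines, 38 genes differed with running, 26 higher and 12 lower. Among the clearest were Pde4d (0.60, SE 0.08, adjusted p = 0.000112), Rcan2 (0.48, SE 0.07, adjusted p = 0.000784) and Kyat3 (0.78, SE 0.13, adjusted p = 0.00192), each called in all 26 refits without 1 library. The glycolytic aldolase Aldoc (1.25), the insulin receptor adaptor Grb14 (0.53), Sv2b (0.49) and the insulin-responsive glucose transporter Slc2a4 (0.29) also rose. So did Eno3 (0.36), the complex III subunit Uqcrh (0.26) and counts at the small nucleolar RNA gene Snord13 (0.55). With priming from the poly(A) tail, counts at Snord13 need not come from the mature small nucleolar RNA. Osgin1 (-1.05), Catsper4 (-0.90), the small GTPase Rhob (-0.76), Dusp1 (-0.70), Btrc (-0.51), Actg1 (-0.46), Tra2a (-0.39) and Vcpip1 (-0.35) fell. Chosen after their values were seen, Tsc22d3 (0.45, adjusted p = 0.00551), Nfkbia (0.38), Klf9 (0.34) and Glul (0.33) were higher.

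**Figure D3:**
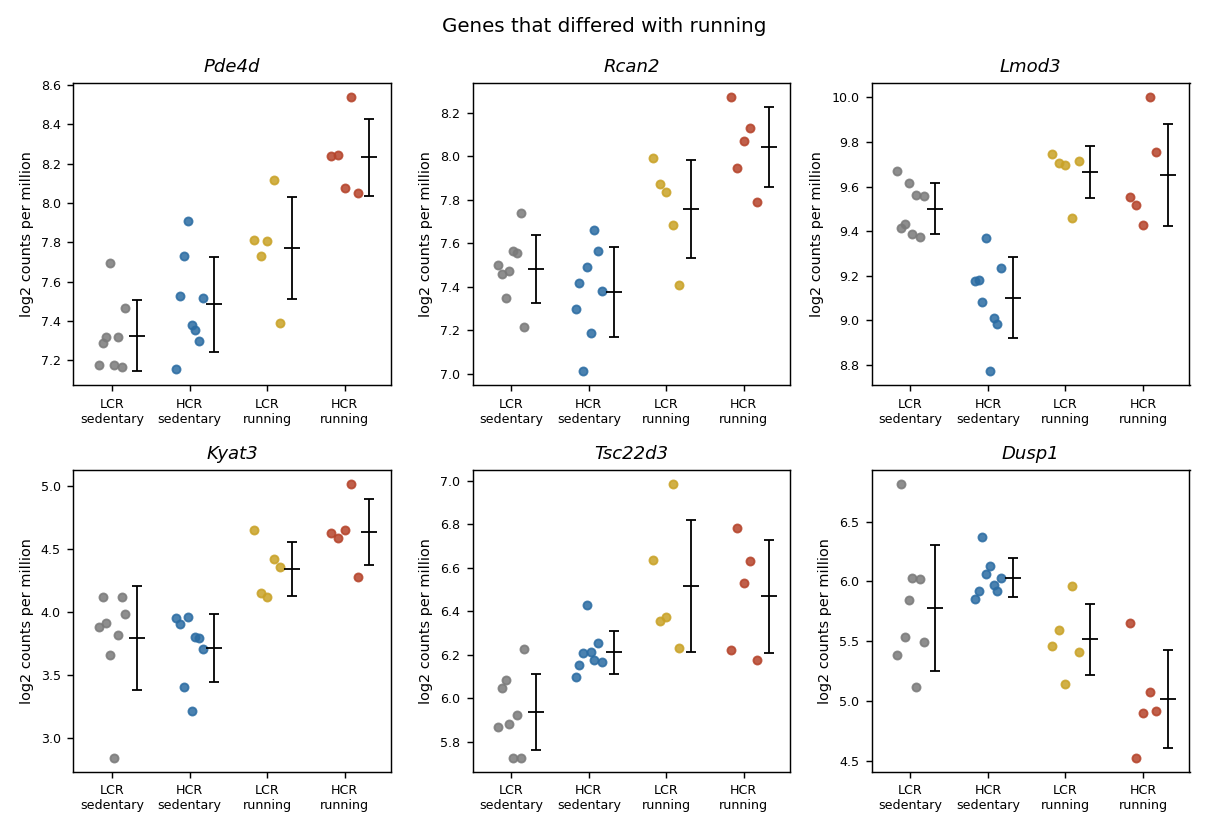
Log2 CPM (y axis) of 6 genes in each library of the 4 groups (x axis), with points for libraries and a bar for the mean and SD. For Pde4d, Rcan2 and Kyat3 the 5 HCR runners lie above all 8 sedentary HCR rats.

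Nuclear OXPHOS subunits lay higher over both lines, 75 of 78 above 0 (median 0.15, adjusted p = 4.55e-19; p = 0.407 with an estimated correlation), with 1 past the threshold and 12 when adjusted over the list alone. Glycolysis (adjusted p = 0.000159), atrophy genes (adjusted p = 0.00645), the TCA cycle (adjusted p = 0.000289) and mitochondrial quality control (adjusted p = 0.0168) lay higher. Immediate early genes (median -0.22, adjusted p = 0.000141), collagen and matrix genes (median -0.21, adjusted p = 0.000159), heat shock genes (adjusted p = 0.00561), endothelial markers (adjusted p = 0.00645), pericyte markers (adjusted p = 0.033), interferon response genes (adjusted p = 0.0247) and endoplasmic reticulum stress genes (adjusted p = 0.0247) lay lower. With an estimated correlation their p-values were 0.407 or above. Interferon response genes did not pass without the 2 libraries with conflicting titles (adjusted p = 0.314).

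The averaged count ran from 9 without LCR running 1 to 63 without LCR running 5, and 23 of the 26 refits moved it by more than 1.5 times. DESeq2 called 80 genes, with upper-quartile factors 17 of 32 calls were higher (53.1%), and without the 2 libraries with conflicting titles 24 of 43 (55.8%). Uqcrh kept its call in 1 of the 26 refits, Slc2a4 in 3, Dusp1, Snord13 and Eno3 in 5 each, Aldoc, Catsper4, Sv2b and Tra2a in 6 each, Btrc and Rhob in 7, Osgin1 in 8, Grb14 in 10, Vcpip1 in 11 and Actg1 in 12, and with the replicate block 14 of the 38 calls were shared.

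The difference between the lines' responses to running was tested directly. Running here means access to a wheel, and the distance run by each animal was not analysed. A difference in the amount run therefore cannot be separated from a difference in response. No gene passed (edgeR, smallest adjusted p = 0.835), DESeq2 and voom called 0, and 592 genes had an unadjusted p under 0.05 against 503 expected. The genes of smallest p were Ptn (-1.74, SE 0.43), Fbxo33 (-1.20), Usp36 (0.51), Zbtb4 (-0.44) and Tollip (-0.82). Myh2 stood at -1.78 (SE 0.71) and Angptl4 at 3.90 (SE 1.21), both with adjusted p = 0.835. So the running differences called in HCR and not in LCR are not shown to differ between the lines.

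A further question was whether running moved LCR rats towards sedentary HCR rats. With the LCR controls split so that no library served both differences, the covariance across genes was -0.000198 (permutation p = 0.963 over all 1287 relabellings of the LCR libraries). With shared controls it was 0.0155, against 0.016 with no effect, a difference of -0.000489. No such shift was detectable. Across genes the running differences of the lines correlated with r = 0.229, and all 10 HCR calls had the same sign in LCR.

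Of the 32 lists, 10 passed in no comparison with camera and the preset correlation. Fry's test of change in either direction called 2 of these 10, antioxidant genes between the sedentary lines (adjusted p = 3.16e-06) and exercise-responsive regulators between the sedentary lines (0.00759), in LCR running (0.0136) and in running averaged (0.0348). The smallest camera adjusted p of the 10, over the 6 comparisons, was 0.14 for senescence and p53 targets, 0.181 for denervation and neuromuscular junction genes, 0.223 for proteasome subunits, 0.326 for erythrocyte markers, 0.36 for antioxidant genes, 0.414 for exercise-responsive regulators, 0.43 for circadian clock genes, 0.536 for neutrophil markers, 0.61 for satellite cell genes and 0.6252 for lymphocyte markers. After the expression filter only 1 neutrophil marker, 1 lymphocyte marker and 5 erythrocyte markers were tested, so these lists say little about those cells. In the denervation list Chrng, the fetal acetylcholine receptor subunit, ran from 1.69 to 6.34 log2 CPM within sedentary LCR.

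**Figure D4:**
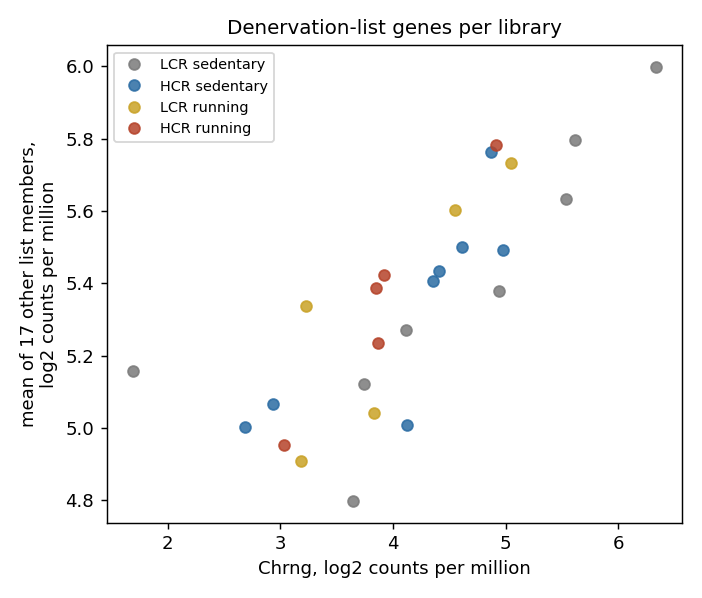
Log2 CPM of Chrng (x axis) against the mean log2 CPM of 17 other denervation list members (y axis), with 1 point per library in each of the 4 groups. Sedentary LCR libraries hold both the lowest and the highest Chrng.

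Vegfa, an angiogenic factor, stood between -0.23 and 0.00 in the line and running contrasts, and Cs, citrate synthase, between 0.01 and 0.14.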

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

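The tests of the 2 libraries with conflicting titles, of mislabelled samples, of LCR RNA in HCR running 4 and of dissected fast muscle were chosen after the results were seen. The tests of neighbouring line genes in HCR running 4, of depth and of regrouping were set before, but the random draws of the neighbour test were corrected after a first result was seen (share 0.0617 before, 0.112 after).

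Within groups, 284 sets of values were searched for a library far from the others, and 19 were found. Chance alone would give about 5% of the 284. Of the 19, 9 lay in LCR sedentary 5. There, log2 CPM was 7.24 for Acsl1, 8.56 for Eno3, 13.09 for Myh7, 9.86 for Myh2, 8.14 for Cpt1b, 2.84 for Kyat3, 4.67 for Sv2b and 9.15 for Slc2a4, each below the other 7 libraries, and the 10 most abundant genes took 19.4% of counts against at least 21.4% in the others. Other values far from their group were Ptn at 1.87 and Actg1 at 4.01 in LCR sedentary 7, Cdv3l1 at 3.25 in LCR sedentary 3, Vcpip1 at 5.39 in LCR sedentary 2 and Rps28 at 8.88 in HCR sedentary 5. Among runners they were Cdv3l1 at 4.92 in LCR running 5, Lmod3 at 9.46 in LCR running 4, G3bp2 at 6.95 in LCR running 3 and Acad11 at 2.80 in HCR running 4. Prmt1 stood at 2.79 in LCR sedentary 8, where the other sedentary LCR libraries lay between 5.77 and 7.08.

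For the difference between the lines' responses to running, 12 lists passed with camera and the preset correlation only. Adjusted p was 6.4e-10 for collagen and matrix genes, 3.00e-07 for ribosomal proteins, 1.13e-06 for fatty acid genes, 6.07e-05 for MHC class II, 6.1e-05 for immediate early genes, 0.000166 for both OXPHOS subunits and macrophage markers, 0.0153 for fibro-adipogenic markers, 0.0272 for both glycolysis and slow-fibre genes, and 0.0327 for both fast-fibre genes and Schwann cell markers. With an estimated correlation the smallest adjusted p was 0.548, and no single gene passed. With fry's test for a shared direction it was 0.517, and fry's test of change in either direction passed 0 lists. A difference of responses is therefore not shown for these lists. Collagen genes had all 30 members below 0 and fatty acid genes 31 of 32 above 0 in the HCR minus LCR response.

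HCR running 4 carried Prmt1 at 6.27 log2 CPM, at the LCR level. For HCR running 4, 29 of the 41 other line genes lay nearer HCR (70.7%), short of the 75% bound set first, so the median position from HCR (0) to LCR (1) was examined afterwards, and it was 0.126, which argues against a wrong label. The other 15 genes higher in LCR had a median position of -0.0698, with Prmt1 at 1.07, which argues against admixed LCR RNA. An LCR allele segregating within HCR stays open: LCR-like neighbours were sought within 10 genes in GRCr8 order among 2-fold line genes (3 pairs against 1.24 in random draws, share 0.112), but 0 other genes searched lay that near Prmt1, so the test could not speak to it. The called line gene next to Prmt1, Ap2a1 (-0.59 in sedentary HCR), differed by less than 2-fold and was not searched. The 3 pairs included Acad11 with Ackr4, at positions 0.851 and 0.801 in HCR running 4. In LCR sedentary 8, 84.8% of 33 other line genes lay nearer LCR, against a wrong label.

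The titles of HCR running 5 and LCR running 5 name the other line. HCR running 5 lay nearer HCR at 70.7% of 41 line genes, short of the 75% bound set first, and LCR running 5 nearer LCR at 82.9%. The median position, examined after that, was 0.0915 for HCR running 5 and 1.02 for LCR running 5, on the genotype side of the midpoint by 17.1 and 4.23 SD of the other 4 runners of the line, which argues against the titles. The line genes were chosen on sedentary libraries alone.

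The lower fast-fibre genes of HCR runners were weighed against fast muscle dissected with the soleus of LCR runners. Myh4, Myh1, Pvalb and Actn3, abundant in such muscle, had a median log2 fold change of -0.41, from -0.62 to 0.59 without 1 library, against -2.86 for Myh2, which argues against it as the whole cause. The SE of these 4 genes were 0.77, 0.76, 0.76 and 0.55, so a part played by such muscle stays open. With all libraries thinned to the shallowest total of 1.10 M counts, the largest adjusted p of Myh2, Tnni2 and Tnnt3 was 0.0223 and Myh2 stood at -2.83, which argues against depth. Other causes stay open and were not tested.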

How the results depend on the processing

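The alternatives were set before the data were examined, except the replicate block in the list tests, chosen after seeing the data. Each count below is of genes or lists past the threshold, and the cause of a change was not tested unless stated. HCR against LCR runners (63): 35 with the stricter filter, 35 with only the 2 groups, 0 with the title's line and 35 without both conflicting libraries; 32 to 67 without 1 library. LCR runners (0): 2 with DESeq2, 1 with voom, 2 with no filter and 1 without both conflicting libraries; 0 to 2 without 1 library. HCR runners (10): 79 with DESeq2; 4 to 38 without 1 library. Running averaged (38): 80 with DESeq2 and 19 with the replicate block; 9 to 63 without 1 library. The sedentary lines (274) ran from 182 to 337 without 1 library, and the difference of responses stayed at 0. With an estimated correlation and with directional fry, list counts of 8, 7, 8, 15, 12 and 12 became 0. The shift covariance of -0.000198 was 0.0155 with shared controls, which add covariance, and 0.00217 without LCR running 5 (permutation p = 0.636).

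Same-numbered replicates correlated between -0.221 and 0.257 across genes, which gives no sign that the numbers pair the animals. Pairing that touches few genes would not be seen this way and stays possible. With the replicate block the counts were 253, 53, 0, 12, 19 and 0, and the lists 8, 6, 7, 18, 15 and 12.

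No called gene reported under the fixed naming rule reversed; other called genes, named or not, were not followed. Uncalled values that changed sign were, in the sedentary lines, Vegfa (0.0102 with upper quartile, 0.0166 with voom, 0.0057 with the stricter filter, 0.0017 with 2 groups; -0.0597 to 0.0696 without 1 library), Myh1 (-0.12 with the block; -0.30 to 0.29), Myh4 (-0.38 to 0.12) and Cpt1b (-0.11 to 0.0134). In runners by line they were Vegfa (0.14 with the title's line, 0.0514 without both libraries; -0.20 to 0.10), RT1-DMb (0.18) and Myh7 (-0.0247) with the title's line, Cs (-0.0033 to 0.11), Myh1 (-0.97 to 0.63) and Myh4 (-0.49 to 1.68). In LCR runners they were Myh2 (-0.16 with voom, -0.10 with the block, -0.50 with the title's line, -0.27 without both; -0.27 to 0.23), Pdk4 (0.13 with the title's line) and Cpt1b (-0.0149 without both; -0.0196 to 0.13). In HCR runners they were Cs (-0.0192 with upper quartile, -0.0020 with the stricter filter; -0.0085 to 0.0357) and Myh4 (-1.08 to 0.66). In the difference of responses with the title's line they were Tnni2 (0.35), Myh2 (0.41) and Tnnt3 (0.10). With totals of 1.10 to 2.52 M counts, 1.5-fold changes were recovered for 6.5% of genes in the difference of responses.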

Other observations

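The correlation among denervation genes and its test were chosen after the values were seen. The tests of glucocorticoid targets, of gene order and of regrouping were set before their results.

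Genes of denervated muscle varied widely between animals of the same group. Chrng, the fetal subunit of the acetylcholine receptor, ran from 1.69 to 6.34 log2 CPM in sedentary LCR and from 2.69 to 4.97 in sedentary HCR (n = 8 each). The 6.34 is LCR sedentary 5, the library with 9 of the 19 values found far from their group. After removing group means, Chrng followed the mean of 17 other list members over 26 libraries, with Pearson's r = 0.808 and Spearman's rho = 0.874 (2 members seen when the pattern was found were left out, and with all 19 r was 0.8292; permutation p = 1e-05 for both, the smallest the resamples can give, 2e-05 adjusted over the 2 relations computed). Without LCR sedentary 5 r was 0.769, without the 2 libraries farthest in Chrng 0.863, and within sedentary LCR and HCR it was 0.794 and 0.826. The same mean did not follow library depth detectably (r = 0.178, p = 0.382; rho = 0.16, p = 0.431). Genes of other lists vary together too: the estimated correlation among members was 0.338 here, 0.49 for OXPHOS subunits and 0.524 for collagen genes, so the relation is not special to this list. A candidate explanation, among others, is partial denervation that differs between aged animals; no measure of innervation was analysed here.

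Several genes higher in runners are known targets of the glucocorticoid receptor, among them Tsc22d3, Klf9, Nfkbia and Glul. Other targets seen when the idea was formed lay above 0 on average but did not pass. These were Fbxo32, Ddit4, Klf15, Trim63, Pdk4, Angptl4, Mt1 and Mt2A, with edgeR adjusted p from 0.0549 (Fbxo32) to 0.936 (Angptl4). In LCR runners Trim63 (-0.033), Pdk4 (-0.28) and Angptl4 (-1.69) lay below 0 and the rest of these above 0. As a test, 19 measured targets not used to form the idea were examined. Their median log2 difference with running, averaged over both lines, was 0.12 (2-sided permutation p = 0.0347), with 14 of 19 fitted values above 0, and none passed alone (Errfi1 0.59, adjusted p = 0.0986). Foxo1, Foxo3 and Eif4ebp1 of the 19 also belong to the atrophy list, which lay higher in runners, so the set is not independent of that result. Per1 stood at -0.0029 and Sgk1 at -0.022, both among the 19. Dusp1, a target too, was lower. Higher glucocorticoid signalling in runners at sampling is a hypothesis for the higher median of the 19. Time of day and handling at sampling are not given in the sources used here and may act alike.

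Genes that differ between the sedentary lines lay next to each other more often than expected. Of 264 line genes placed in GRCr8 order among 9790 tested genes, 16 adjacent pairs were found, against 7.06 on average in random sets matched on expression (share of 10000 sets with as many, 0.0018). Of the 16, 11 had the same direction, such as Acad11 with Ackr4, and 5 opposite directions, such as Hook1 with Cyp2j4. Linked variants that differ between the lines may account for this, as may reads shared between overlapping neighbours, which were not separated here. The random sets were matched on expression level alone, so neighbouring genes that vary together for other reasons were not accounted for.

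Other splits of the same libraries, 100 per comparison with the real one included, were counted. For the sedentary lines 1 split, the real one with 274 genes, gave as many (highest other 25). The same held for the running lines (63, highest other 5), HCR running (10, highest other 4) and running averaged (38, highest other 3). A share of 1 in 100 is the smallest these splits can give, so chance regrouping is made unlikely but is not excluded. Without HCR running 3 the HCR running count was 4, no more than the highest other split of all libraries. For LCR running and for the difference of responses, with 0 genes, all 100 give as many by construction (highest other 1 and 3), so the splits say nothing about chance there.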
